A study of Mus musculus with 7 samples.

How the data were processed

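The series holds 7 arrays of mouse RNA, 1 array per sample, from 10 mice. Per the labels, the cells were sorted by flow cytometry from dorsal skin at postnatal day 15, total RNA was extracted and quality-checked, and a small input was linearly amplified, labelled with a single dye and hybridised to a mouse expression array. Groups were taken from the sample titles: 3 arrays labelled control and 4 labelled cΔex3, the β-catenin activation group, with mice pooled on 1 and on 2 of them. The labels call the samples biological replicates of separate mice, so that the spread between arrays includes that between animals.

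Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1 as 1 scan of 1 slide. The deposited intensity used here is the processed signal, which per the file headers is background-subtracted and spatially detrended, on a linear scale and not normalised between arrays. Raw median spot intensity and local background intensity from the same deposited files served 1 alternative, and deposited flags per spot (other values, 0 or 1) gave saturation, outliers and whether a spot was well above background. The authors also deposited a table of log2 values for the whole series; its making is not stated. Its columns had nearly equal distributions, as quantile normalisation gives, with medians between 7.407 and 7.413, and correlated at 0.9999 with each array's own values after normexp and quantile normalisation, so that its scale is log2; its background offset stays unknown, and it was used as an alternative only.

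The slide number in the header differed from that in the file's name on 7 of 7 arrays and the slide position on 4. The header's slide number held the design number of the array layout on 7 of 7 arrays and the one in the file's name on 0. Each file's sample was taken from the deposit's own record.

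Values were log2 of the processed signal minus each array's 75th percentile. Control spots and spots with an outlier mark were left out and spots of 1 probe were averaged, which left 55681 probes, of which 49 had no value on some array. Probes were named through their accession and a RefSeq gene table on GRCm38.p6; the array's own annotation uses another build, so that no coordinates are given. Of 28167 probes with a RefSeq transcript accession, 27793 matched a gene, 28026 probes had a gene name and 27655 had none here. A probe was tested where it was well above background on at least 3 of 7 arrays, which 42429 probes were, 23743 of them named. Per gene the probe with the highest mean over all arrays was used, giving 18026 genes. Of 4744 genes with several tested probes, 181 had probes past the threshold in both directions, among them Nkd2, Fgf11 and Mbp of the named genes.

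The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene not well above background on any array of a group has only a bound there, given as at least N-fold: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the array's lowest signal among probes well above background and the probe's own. All p-values and adjusted p-values printed for genes come from limma. Beside a bound they belong to the fitted difference, which uses signals not well above background, and not to the bound. Gene lists with at least 3 tested members were compared with limma's camera at a preset correlation of 0.01, adjusted over 32 lists, with camera at an estimated correlation and fry beside it. The lists hold Wnt targets and ligands, BMP, FGF, Notch, TGF-β, hedgehog and other growth factor genes, matrix, contractile, protease, cell cycle, skeletal, cytokine, interferon and stress genes, and markers of the follicle's dermal compartments and of the other cells that the sort could hold. Of 574 list genes, 573 matched a gene name and 526 were tested. A further 10 lists (hepatocyte, epididymis, mesothelium, brown adipocyte, kidney, heart, exocrine pancreas, lung, intestine and testis) were written after the brightest and most changed genes had been seen; they share no gene with the others and were not tested with camera.

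The genes to name were chosen by a rule fixed before the data were examined, and 2 of the 154 chosen are left out of the text. They are the 10 largest rises and 10 largest falls among genes past the threshold, without overlap between the groups' arrays and above background on every array of the higher group, with 0 passed over for an unnamed symbol in either direction; the up to 4 tested members of each list with the smallest p; and always Ctnnb1, Cd34, Alpl, Itga8, Axin2, Lef1, Acta2, Col1a1 and Mki67. Hepatocyte, mesothelium, epididymis and testis genes, Cfd and Xist were named after their values had been seen.

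The steps were tested on simulated data for this comparison over 18026 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The share recovered was 18% at 2-fold and 67% at 4-fold, with 5 false calls among 90 and a median error of 0.182 on the log2 scale. Of 32 simulated lists the 1 that was shifted was called, and 0 of the other 31 were called by camera. The simulated noise was independent between genes. In the data the estimated correlation ran from −0.088 for the melanocyte list to 0.84 for the interferon list. The simulation therefore does not test camera's false calls among correlated genes. It also changed far fewer genes than the 53.1% called in the data, so its recovery rates may not carry over.

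Alternatives fixed in advance were quantile normalisation, normexp with an offset of 50 and quantile normalisation, centring on the median, no filter on dim probes, probes above background on all 7 arrays, the mean of a gene's probes, eBayes with trend and robust options, array weights, the replicate number as a block, a covariate for pooled mice, arrays of 1 mouse only, the deposited series values, a covariate from the Y-linked genes, a 2-fold minimum, and leaving out each array in turn. Normexp used the median spot signal, in place of the mean spot signal that had been planned, which was not used here. Slide row as a block, each slide row alone, and the fit without cΔex3-labelled arrays 1 and 4 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.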

Results

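The dermal sheath is the layer of mesenchymal cells that wraps the hair follicle. By its title, the study asked what activation of β-catenin, the transcriptional effector of Wnt signalling, does in this layer. By their labels, dermal sheath cells were sorted at postnatal day 15 from dorsal skin as cells positive for the YFP reporter and negative for CD34, alkaline phosphatase and integrin α8. Their RNA was hybridised to 1-colour mouse arrays. There were 3 arrays labelled control, from 4 mice with 2 of them pooled on array 3, and 4 arrays labelled cΔex3, the β-catenin activation group, from 6 mice with 2 pooled on array 2 and 2 on array 3. The 75th percentile of the processed signal was 763, 756 and 907 on the control-labelled arrays and 1858, 1348, 1659 and 2160 on the cΔex3-labelled arrays. Probes well above background made up 71.5%, 69.6% and 69.3% of the former and 81.6%, 69%, 70.8% and 82.7% of the latter, and 0 spots were saturated. Every difference below is cΔex3-labelled minus control-labelled on the log2 scale, and the number of arrays limits its precision. Values are relative to the array's 75th percentile, which was higher on every cΔex3-labelled array. An equal processed signal therefore reads lower there, which limits what small falls of dim genes can mean.

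The arrays carried abundant transcripts of cells other than those that the labels name. The control-labelled arrays were led by transcripts of hepatocytes, the main cells of the liver. Albumin (Alb) was the brightest named gene there, at 9.74 ± 0.19 (SD, n = 3) relative to the array's 75th percentile, and ranked 5688 on the cΔex3-labelled arrays, at 1.44 ± 1.496 (SD, n = 4). All 20 members of a hepatocyte list, written after the brightest genes had been seen, were lower on the cΔex3-labelled arrays (limma), with a median of −9.04. Of these, Cyp2e1 lost the threshold in 8 of 24 other settings, over a range of −4.05 to −1.51. The list's median lay at the 99.8th percentile of named genes on each of the 3 control-labelled arrays and between the 38.7th and 67.4th on the others. Adipocyte transcripts were among the brightest on the cΔex3-labelled arrays, where complement factor D (Cfd) ranked 3 against 4278 and the fatty acid binding protein gene Fabp4 ranked 8 against 4102. The adipocyte list, fixed before the data were examined, had its median between the 99.1th and 99.9th percentile there and between the 70.9th and 83.7th on the control-labelled arrays. Groups are named by their labels throughout, and no difference below is read as an effect of the allele on dermal sheath cells.

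**Figure D1:**
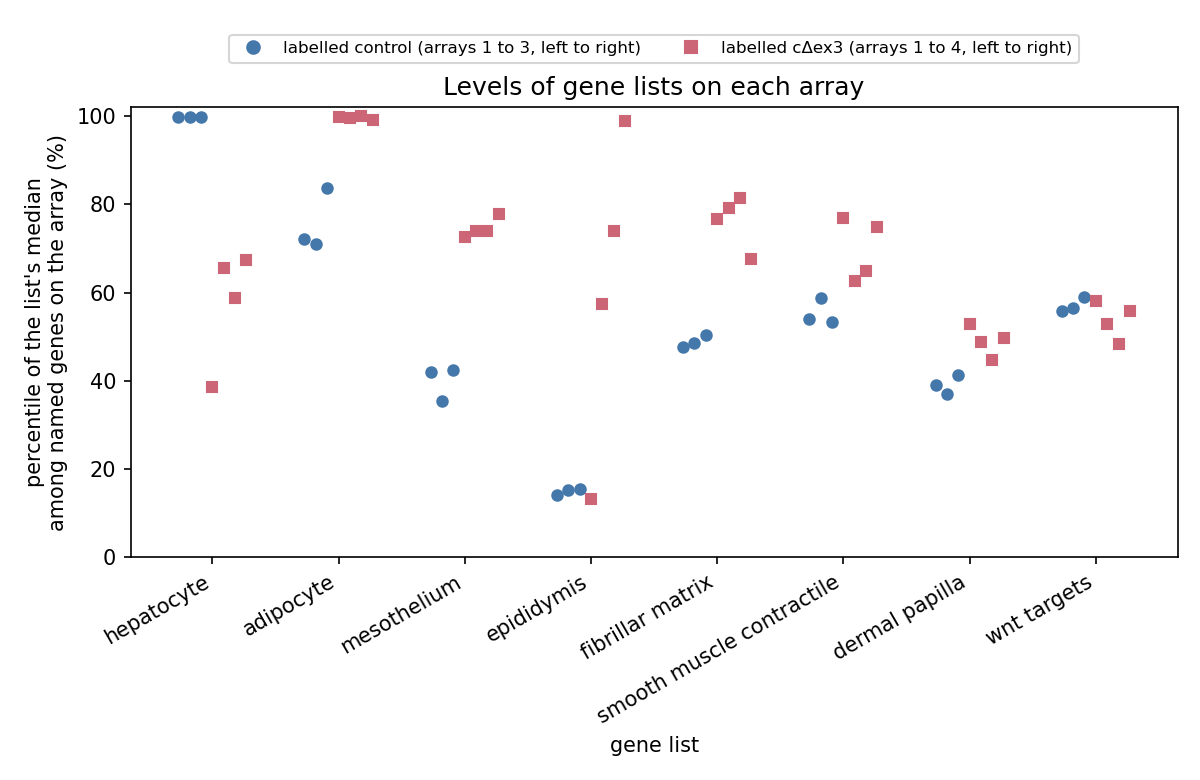
Median level of 8 gene lists on each array, given as a percentile (%) of all named genes on that array, with circles for arrays labelled control (n = 3) and squares for arrays labelled cΔex3 (n = 4), in array order from left to right. The hepatocyte list lies at 99.8 on all 3 control-labelled arrays, the adipocyte list between 99.1 and 99.9 on all 4 cΔex3-labelled arrays, and the epididymis list between 13.3 and 98.8 on the latter.

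The gene that the allele alters and the genes of the sort were well above background on all 7 arrays. Ctnnb1, which encodes β-catenin, differed by −0.02 ± 0.14 (SE; limma, adjusted p = 0.902), at 3.46 ± 0.01 (SD, n = 3) on the control-labelled and 3.44 ± 0.05 (SD, n = 4) on the cΔex3-labelled arrays, and by 0.47 with quantile normalisation. With normexp it was 0.53 higher (adjusted p = 0.0241) and in the deposited series values 0.52, both past the threshold, where the adjusted p of its alternatives ranged up to 0.984. Ctnnb1 was read by 1 probe whose exon is not known here, and a probe outside the deleted part of the gene checks nothing about the allele. Cd34, whose protein the sort excluded, rose by 4.84 ± 0.31 (SE; adjusted p = 4.49e-05) and was higher on 4 of 4 arrays. Alpl, the gene of tissue-nonspecific alkaline phosphatase, differed by −1.27 ± 0.98 (SE; adjusted p = 0.308) and Itga8 by −0.77 ± 0.61 (SE; adjusted p = 0.323), or 0.39 with arrays of 1 mouse only. Y-linked transcripts were above background in both groups. Eif2s3y fell by 1.18 (adjusted p = 0.0144), a call that was lost without control array 2 (−1.13) or 3 (−1.06), whereas Ddx3y at −0.50, Uty at −0.21 and Kdm5d at −0.29, the last above background on 3 of 4 cΔex3-labelled arrays, did not pass the threshold. Xist, the transcript that silences an X chromosome in females, was above background in 3 of 14 pairs of probe and array.

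**Figure D2:**
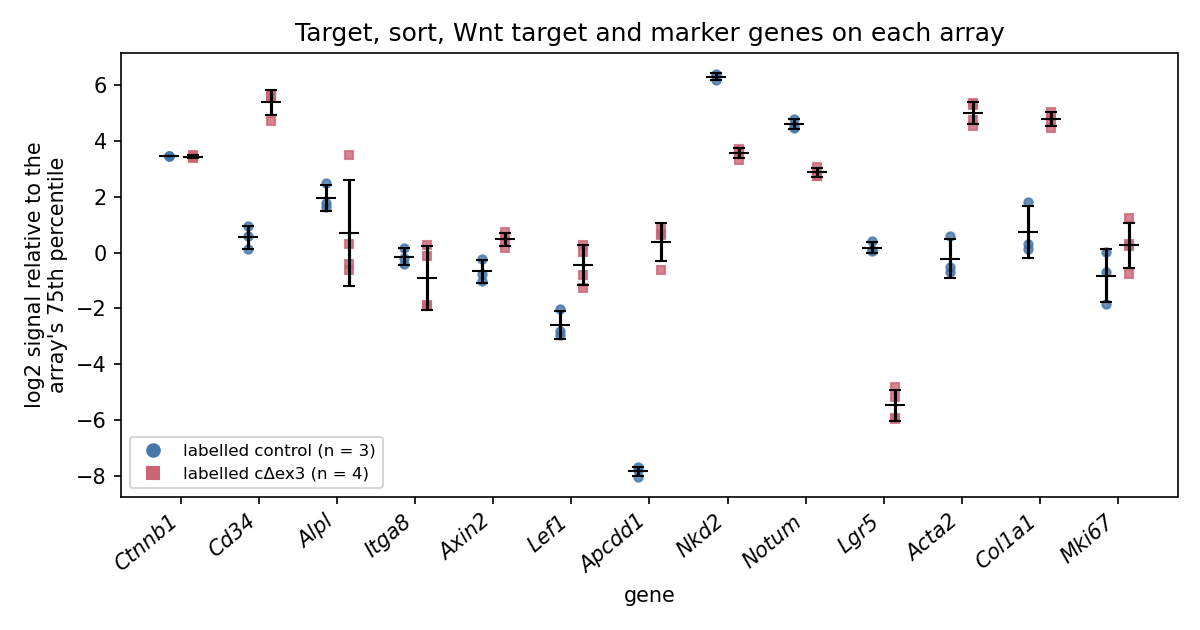
Log2 signal relative to the array's 75th percentile of 13 genes on each array, with circles for arrays labelled control (n = 3), squares for arrays labelled cΔex3 (n = 4), horizontal lines for means and bars for ± 1 SD. Ctnnb1 lies at 3.46 and 3.44 in the 2 groups. On the arrays labelled cΔex3, Cd34, Acta2 and Col1a1 are higher, and Lgr5, Notum and the plotted probe of Nkd2 are lower. The other probe of Nkd2, not drawn, was 3.10 higher there. Apcdd1 was not well above background on the control-labelled arrays.

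Of 18026 genes tested, 4333 were higher and 5236 lower on the cΔex3-labelled arrays, together 53.1% (limma, adjusted p under 0.05, n = 3 and 4). At least a 2-fold difference was found for 3624 of the higher and 3641 of the lower genes, and at least an 8-fold difference for 1249 and 969. The arrays of the groups did not overlap for 10583 genes, where chance gives 5.71% of genes, and 9269 of these passed the threshold. Correlations across genes, which are not independent replicates, were 0.980 to 0.9845 within the control-labelled arrays, 0.938 to 0.975 within the cΔex3-labelled arrays and 0.8115 to 0.863 between them. The first principal component held 77.6% of the variance and separated the groups. With the mean of the Y-linked genes as a covariate the counts were 721 higher and 1014 lower. That mean was itself higher on every control-labelled array than on any cΔex3-labelled array, so it partly stands for the labels. Within the lower row of the slide, which held 1 control-labelled array, all 9569 called genes kept their direction. This was nearly fixed in advance, since the genes were called on these same arrays and 9269 of them did not overlap between the groups. SEs of the 154 genes chosen by the fixed rule ranged from 0.137 to 1.62, with a median of 0.356, and 95 of these genes were higher, 48 lower and 11 not past the threshold.

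The 10 largest rises by the fixed rule included adipocyte genes. Adipoq, which encodes the adipocyte hormone adiponectin, rose by 11.43 ± 0.78 (SE; adjusted p = 5.83e-05), from −3.86 ± 1.68 (SD, n = 3) to 7.56 ± 0.71 (SD, n = 4). Retn (resistin) rose by 10.01, Plin1 (perilipin 1, a coat protein of lipid droplets) by 10.02, the amine oxidase gene Aoc3 by 10.06, Arxes2 by 10.51 and Nnat (neuronatin), above background on 1 of 3 control-labelled arrays, by 10.09. For 4 of the 10 no control-labelled array was well above background and only a bound holds. Slc7a10, an amino acid transporter gene, was at least 1015-fold higher (adjusted p = 1.53e-05) and Cuzd1 at least 436-fold (adjusted p = 0.000501), or 185-fold without cΔex3-labelled array 4. Arxes1 was at least 344.4-fold higher (adjusted p = 2.21e-05) and Mc2r, the corticotropin receptor gene, at least 344.2-fold (adjusted p = 3.56e-05). The adjusted p of the 10 genes ran from 9.30e-06 to 0.000501, and each was higher on 4 of 4 arrays. Cuzd1 was also on the epididymis list described among the other observations.

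The 10 largest falls, of which 9 are named here, included enzymes and secreted proteins of the liver. Otc, a urea cycle enzyme, fell by 10.82 ± 0.96 (SE; adjusted p = 0.000167). Hsd17b13, a lipid droplet enzyme, fell by 11.43. The difference was −10.88 for the mitochondrial carbonic anhydrase gene Car5a, −11.04 for the collectin gene Colec10, −10.88 for the Kupffer cell receptor gene Clec4f and −11.05 for the transporter gene Slc17a2. These 6 genes were above background on only 1 to 3 of the 4 cΔex3-labelled arrays, and another probe of Hsd17b13 differed by −0.88. Pax2, a transcription factor gene, fell by 11.26. Baat, which conjugates bile acids, was at least 563-fold lower (adjusted p = 8.99e-06) and Cyp8b1, an enzyme of bile acid synthesis, at least 427-fold lower (adjusted p = 7.56e-06), with no cΔex3-labelled array well above background. The adjusted p of the 9 falls named here ran from 7.56e-06 to 0.000195.

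Among 32 gene lists fixed before the data were examined, 10 lay higher than the other genes on the cΔex3-labelled arrays with limma's camera at a preset correlation of 0.01, and 0 lay lower; at an unadjusted p under 0.05 camera gave 13 higher and 0 lower. With an estimated correlation none of the 10 passed, their adjusted p lying between 0.431 and 0.6985, and 2 had an unadjusted p under 0.05. The test fry, which asks whether a list's genes move one way without setting them against other genes, gave 18 lists higher and 4 lower, the former holding all 10 lists that camera called, at adjusted p of 0.000169 to 0.0217. Leaving out control array 2 made interferon-stimulated genes lower by camera (adjusted p = 0.0116, with a range of 0.000912 to 0.5675 over 24 other settings). Counts of list members below are adjusted over all genes tested. Of those 18026 genes, 24% were called higher and 5236 genes lower, so a list with like shares does not stand out by its counts. The counts adjusted over the list alone were equal for 23 lists and are given beside the others. In every list the differences stood between arrays led by hepatocyte transcripts, with a list median of −9.04, and arrays with high adipocyte transcripts, with a list median of 5.72.

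**Figure D3:**
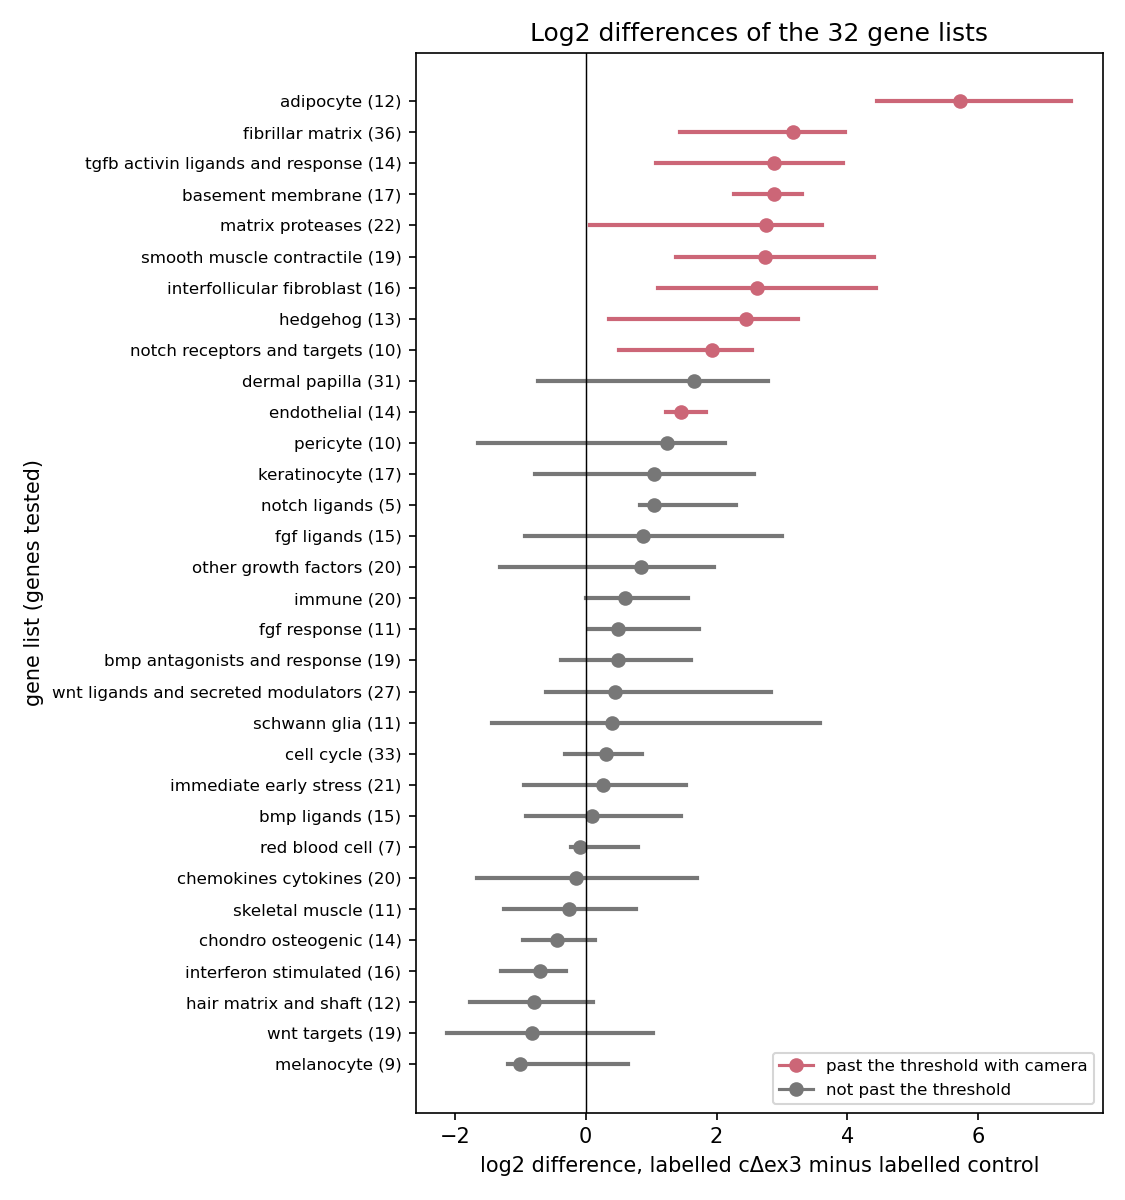
Median log2 difference (points) and interquartile range (lines) of the tested members of 32 gene lists, arrays labelled cΔex3 minus arrays labelled control, with the number of tested genes in parentheses and colour for the lists past the threshold with camera. The adipocyte list has the highest median, 5.72, and the 10 coloured lists have positive medians.

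Some calls of single genes were marginal and changed when 1 array was left out. Actn3 was not past the threshold, at 2.06 to 3.45, without any array but control array 1, and Hbb-b1, at 0.83 to 1.13, without any but cΔex3-labelled array 4. Gpr143 lost its call without control array 1 (−1.48) or 2 (−1.87) or cΔex3-labelled array 1 (−1.75). Irf7 did so without control array 1 (−1.34) or 3 (−1.28) or cΔex3-labelled array 1 (−1.55), Dll3 without control array 2 (−0.98) or 3 (−0.97), and Usp18 without control array 1 (−2.11). Acta1 gained a call without control array 1 (4.68), Ddx3y without cΔex3-labelled array 3 (−0.63), and Alpl (−2.20), Hbb-bt (0.83) and Kit (0.82) without cΔex3-labelled array 4. Where another probe of a gene differed from the one used by over 1 on the log2 scale in the same direction and is not given elsewhere, it gave 1.59 for Pdgfb, 3.12 for Ltbp3, 5.30 for Fgf18, 2.65 for Etv1, 4.33 for Trp63, 5.30 for Lox, 6.37 for Chrdl1, 9.06 for Nnat, 11.52 for Retn and −9.88 for Slc17a2; the other probe of Dll3 differed by 1.26 and did not pass.

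Targets of Wnt/β-catenin signalling went both ways. Of 19 tested, 5 were higher and 6 lower, or 5 and 8 adjusted over the list alone, with a median of −0.83 (camera adjusted p = 0.5475; fry lower, adjusted p = 0.00137). Axin2, a negative-feedback gene of the pathway, rose by 1.14 ± 0.25 (SE; adjusted p = 0.00766), while its other probe, at 0.61, did not pass, and Lef1, a transcription factor that binds β-catenin, by 2.14 ± 0.43 (SE; adjusted p = 0.00556). Apcdd1, which encodes a Wnt inhibitor, was at least 67.9-fold higher (adjusted p = 1.28e-05). Lgr5, the R-spondin receptor gene that marks hepatocytes around the central vein as well as follicle stem cells, fell by 5.66 ± 0.32 (SE; adjusted p = 2.76e-05) and was above background on 2 of 4 cΔex3-labelled arrays. Notum, a secreted Wnt deacylase gene, fell by 1.73 (adjusted p = 0.000269). Nkd2 fell by 2.74 with the brighter of its probes and rose by 3.10 with the other, so its direction is not settled. The hepatocyte list moved with the targets that fell, by a median of −9.04.

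Wnt ligands and secreted modulators counted 11 higher and 6 lower of 27, with a median of 0.45 (camera adjusted p = 0.206; fry higher, adjusted p = 0.00137). Wnt5a rose by 2.94, Wnt9a by 2.72, Rspo1, which encodes a Wnt-enhancing R-spondin, by 6.995 and the frizzled-related gene Sfrp2, above background on 1 of 3 control-labelled arrays, by 6.16. The adipocyte list rose beside them by a median of 5.72.

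Genes of the extracellular matrix and the contractile apparatus rose together. The fibrillar matrix list had 29 of 36 members higher and 1 lower, with a median of 3.17, or 2.91 with 3 members at their bound (camera adjusted p = 1.36e-07; adjusted p = 0.4366 with an estimated correlation). Col1a1 rose by 4.04 ± 0.42 (SE), Col1a2 by 3.72, Col6a1 by 4.58 and the collagen-binding proteoglycan gene Fmod by 3.43, and Lox, which crosslinks collagen, was at least 29.4-fold higher (adjusted p = 4.18e-05). Smooth muscle contractile genes were higher for 16 of 19 and lower for 2, with a median of 2.74, or 2.25 with 2 members at their bound (camera adjusted p = 5.6e-05; adjusted p = 0.431 with an estimated correlation). Acta2, the smooth muscle actin gene and a marker of the dermal sheath, rose by 5.204 ± 0.37 (SE), Myl9 by 4.27, Csrp1 by 2.74 and Synpo2 by 4.57 with its brightest probe and by 3.26 and −0.28 with its others. These lists moved with the adipocyte list, at a median of 5.72, and against the hepatocyte list, at −9.04.

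Basement membrane genes were higher for 13 of 17 and lower for 2, with a median of 2.88 (camera adjusted p = 0.000307; adjusted p = 0.431 with an estimated correlation). The laminin genes Lamb2, Lama2 and Lamb1 rose by 4.66, 3.88 and 3.19, while Col18a1, whose product yields endostatin, fell by 3.19. TGF-β and activin ligands and response genes were higher for 11 of 14 and lower for 0 (limma; also 0 at an unadjusted p under 0.05), with a median of 2.88 (camera adjusted p = 5.6e-05; adjusted p = 0.431 with an estimated correlation). Tgfb3 rose by 3.86 and the latent TGF-β binding protein genes Ltbp1, Ltbp2 and Ltbp3 by 3.24, 4.60 and 5.38. Matrix proteases and their inhibitors were higher for 16 of 22 and lower for 1, with a median of 2.76 (camera adjusted p = 0.000307; adjusted p = 0.4366 with an estimated correlation). The inhibitor genes Timp4 and Timp2 rose by 7.90 and 3.62 and the metalloproteinase genes Mmp11 and Mmp23 by 4.08 and 3.60. All 3 lists rose with the adipocyte list, at 5.72.

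Hedgehog pathway genes were higher for 9 of 13 and lower for 0 (limma; also 0 at an unadjusted p under 0.05), with a median of 2.44, or 1.83 with 1 member at its bound (camera adjusted p = 0.000362; adjusted p = 0.431 with an estimated correlation). The co-receptor genes Cdon and Boc rose by 4.94 and 4.93, and the transcription factor genes Gli3 and Gli1 by 3.07 and 5.05, Gli1 being above background on 2 of 3 control-labelled arrays. Notch receptors and targets were higher for 7 of 10 and lower for 1, with a median of 1.94, or 1.28 with 2 members at their bound (camera adjusted p = 0.0389; adjusted p = 0.431 with an estimated correlation), and the call was lost in 9 of 24 other settings, among them those without control array 1 (adjusted p = 0.0524) or cΔex3-labelled array 1 (adjusted p = 0.0536), over a range of 0.0179 to 0.112. Notch3 rose by 4.15, Notch4 by 2.71 and Heyl by 1.95, and the feedback inhibitor gene Nrarp was at least 11.1-fold higher (adjusted p = 0.001955). Notch ligands were higher for 3 of 5 and lower for 1, with a median of 1.04 (camera adjusted p = 0.127; fry higher, adjusted p = 0.000399). Jag2 was at least 33.0-fold higher (adjusted p = 4.16e-05), Jag1 rose by 2.29 and Dll1 by 1.04, and Dll3 fell by 1.01, a difference of 0.13 with the mean of its probes. The adipocyte list, at 5.72, stood higher on the same arrays.

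BMP ligands were higher for 4 of 15 and lower for 4, with a median of 0.10, or 0.08 with 1 member at its bound, a mean of −0.04 and fry pointing lower (camera adjusted p = 0.665). Gdf2, a BMP made by the liver, fell by 6.55, Bmp5, above background on 3 of 4 cΔex3-labelled arrays, by 3.96 and Bmp2 by 2.24, while Bmp4 rose by 2.78. BMP antagonists and response genes were also higher for 4 and lower for 4, of 19, with a median of 0.49 (camera adjusted p = 0.348; fry higher, adjusted p = 0.0155). The antagonist gene Chrdl1, above background on 1 of 3 control-labelled arrays, rose by 8.33 and Fstl1 by 3.87, Grem1 was at least 22.8-fold higher (adjusted p = 0.000235), and Nog, which encodes noggin, fell by 1.47. FGF ligands were higher for 7 of 15 and lower for 4, with a median of 0.88 (camera adjusted p = 0.252; fry higher, adjusted p = 0.000169). Fgf10 was at least 117-fold higher (adjusted p = 4.77e-05), Fgf7 rose by 2.70 and Fgf18 by 3.39, and Fgf11 rose by 3.29 with the brighter probe and differed by −0.85 with the other. FGF response genes were higher for 5 of 11 and lower for 2, with a median of 0.49, or 0.41 with 1 member at its bound (camera adjusted p = 0.113; fry higher, adjusted p = 0.0224). Spry1 rose by 1.96, Spry2 by 1.90 and Etv1 by 1.55. Spred3 was at least 1.195-fold higher, and its fitted difference was 2.10 (adjusted p = 0.002235). Other growth factors were higher for 9 of 20 and lower for 6, or 10 and 6 adjusted over the list alone, with a median of 0.85 (camera adjusted p = 0.361). Vegfd rose by 4.25, Pdgfb by 3.29 and Edn1 by 2.77. Beside these lists the hepatocyte list differed by a median of −9.04.

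Markers of the dermal papilla, the signalling centre at the base of the follicle, were higher for 13 of 31 and lower for 6, or 14 and 6 adjusted over the list alone, with a median of 1.65, or 0.66 with 5 members at their bound (camera adjusted p = 0.0606; fry higher, adjusted p = 0.00221). The list passed in 9 of 24 other settings, among them those without control array 2 (adjusted p = 0.0493) or 3 (adjusted p = 0.0420) or cΔex3-labelled array 3 (adjusted p = 0.0229), over a range of 0.00712 to 0.3497. Fgf10, Bmp4, Trps1, which rose by 4.00, and Tbx18, at least 8.39-fold higher (adjusted p = 0.0001275), were those with the smallest p. Markers of interfollicular fibroblasts were higher for 12 of 16 and lower for 1, with a median of 2.62 (camera adjusted p = 0.000362; adjusted p = 0.431 with an estimated correlation). Cd34, Pi16, Clec3b and the microfibril gene Mfap5 rose by 4.84, 5.50, 4.30 and 7.84; Cd34 and Pi16 are also expressed by progenitor cells of fat. Adipocyte markers were higher for 10 of 12 and lower for 0 (limma; also 0 at an unadjusted p under 0.05), with a median of 5.72 (camera adjusted p = 5.6e-05; adjusted p = 0.431 with an estimated correlation). Adipoq, Plin1, Retn and Fabp4, the last with a rise of 5.66, had the smallest p.

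Endothelial markers were higher for 11 of 14 and lower for 1, or 12 and 1 adjusted over the list alone, with a median of 1.45 (camera adjusted p = 0.00289; adjusted p = 0.6985 with an estimated correlation). Vwf rose by 2.94, Emcn by 2.81 and the VEGF receptor gene Flt1 by 1.73, and the receptor gene Kdr fell by 1.49 with the brighter probe and differed by 0.63 with the other (−0.43, adjusted p = 0.144, with the mean of both). Pericyte markers were higher for 5 of 10 and lower for 3, or 6 and 3 adjusted over the list alone, with a median of 1.24, a mean of 0.05 and fry pointing lower (camera adjusted p = 0.384). Vtn, which encodes vitronectin, a plasma protein made by the liver, fell by 7.13 ± 0.22 (SE; adjusted p = 7.38e-06), Anpep fell by 2.08, and Cspg4 and Higd1b rose by 3.63 and 2.51. Immune markers were higher for 7 of 20 and lower for 2, with a median of 0.61 (camera adjusted p = 0.113), or an adjusted p of 0.01745 without cΔex3-labelled array 4, in a range of 0.00566 to 0.334. The mast cell genes Mcpt4 and Cpa3, the latter above background on 1 of 3 control-labelled arrays, rose by 6.02 and 5.77, the T cell gene Cd3e fell by 1.36, and Cd207, which encodes langerin and was above background on 1 of 4 cΔex3-labelled arrays, fell by 6.24. Red blood cell genes were higher for 2 of 7 and lower for 1, with a median of −0.08, a mean of 0.006, camera pointing higher and fry lower (camera adjusted p = 0.752). The haemoglobin genes Hba-a1 and Hbb-b1 rose by 1.39 and 0.99, Hbb-bt differed by 0.61 (adjusted p = 0.117), and the haem synthesis gene Alas2 fell by 2.42; haemoglobin genes are near-identical copies whose probes can cross-hybridise. The adipocyte list rose beside these by a median of 5.72 and the hepatocyte list differed by −9.04.

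Keratinocyte markers were higher for 6 of 17 and lower for 3, with a median of 1.05 (camera adjusted p = 0.252; fry higher, adjusted p = 0.0356). Lgals7 was at least 20.8-fold higher (adjusted p = 6.11e-05), and the integrin genes Itga6 and Itgb4 and the epithelial transcription factor gene Trp63 rose by 5.02, 2.47 and 1.96. Hair matrix and shaft genes were higher for 1 of 12 and lower for 6, with a median of −0.78 (camera adjusted p = 0.300; fry lower, adjusted p = 0.0137). The hair keratin genes Krt31, Krt73, Krt28 and Krt27 fell by 1.76, 1.79, 2.04 and 2.12, the last 2 above background on 3 and 2 of 4 cΔex3-labelled arrays. Over 23 other settings Krt28 ranged from −2.37 to −0.78 and Krt27 from −2.48 to −0.74. Melanocyte markers were higher for 0 of 9 and lower for 3 (limma; 3 and 4 at an unadjusted p under 0.05), with a median of −0.998 (camera adjusted p = 0.648; fry lower, adjusted p = 0.00434). The pigment genes Dct and Tyr fell by 4.57 and 1.19, Gpr143, above background on 2 of 4 cΔex3-labelled arrays, fell by 1.80, and Kit differed by 0.64 (adjusted p = 0.057). Schwann and glial markers were higher for 4 of 11 and lower for 4, or 4 and 5 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.641; fry higher, adjusted p = 0.0249). Pmp22 rose by 3.96, or 0.85 with its other probe, and S100b by 3.43, Fabp7 fell by 3.76, and Mbp rose by 3.73 with its brightest probe and by 2.50 and −0.92 with its others. Skeletal muscle genes were higher for 1 of 11 and lower for 1, or 0 and 1 adjusted over the list alone (1 and 1 at an unadjusted p under 0.05), with a median of −0.25, a mean of 0.06 and camera pointing lower (camera adjusted p = 0.865). Pax7 fell by 1.37, Actn3, above background on 1 of 3 control-labelled arrays, rose by 3.16, and Acta1 at 2.75 and Tnnt3 at −2.41 did not pass (adjusted p = 0.1365 and 0.244). Beside the genes that fell the hepatocyte list lay lower by a median of −9.04.

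Cell cycle genes were higher for 4 of 33 and lower for 4, or 0 and 1 adjusted over the list alone (4 and 5 at an unadjusted p under 0.05), with a median of 0.31, or 0.29 with 1 member at its bound (camera adjusted p = 0.531). The list was higher by camera without control array 3 (adjusted p = 0.0420) and pointed lower without control array 2 (adjusted p = 0.992), the ends of its range over 24 other settings. Tpx2 fell by 1.57 with the brighter probe and differed by 1.22 with the other (−0.17, adjusted p = 0.672, with the mean of both). Ccne2, above background on 2 arrays of each group, fell by 1.503, and Bub1b, above background on 1 of 3 control-labelled arrays, rose by 2.69. Aurkb was at least 1.06-fold higher, and its fitted difference was 1.43 (adjusted p = 0.017). Its bound was 0.97-fold, and so no rise, without cΔex3-labelled array 3, and its call was lost in 7 of 23 other settings. Mki67, which encodes the proliferation antigen Ki-67, differed by 1.09 ± 0.58 (SE; adjusted p = 0.151). Cartilage and bone genes were higher for 2 of 14 and lower for 6, with a median of −0.44 (camera adjusted p = 0.374; fry lower, adjusted p = 0.0137). Dlx3, Acan, Sp7 and Sox5 fell by 1.90, 1.67, 0.99 and 0.89. Over 24 other settings Sp7 ranged from −1.47 to −0.56 and Sox5 from −1.11 to −0.02, and Sox5 lost its call in 7. Chemokines and cytokines were higher for 6 of 20 and lower for 5, with a median of −0.14, a mean of 0.41 and camera pointing higher (camera adjusted p = 0.676). Ccl8, Ccl11 and Il33 rose by 6.39, 6.60 and 2.72, Ccl11 being above background on 2 of 3 control-labelled arrays, and Il1b fell by 3.19. Interferon-stimulated genes were higher for 0 of 16 and lower for 4 (limma; 0 and 5 at an unadjusted p under 0.05), with a median of −0.69 (camera adjusted p = 0.252). Bst2, Oasl1, Usp18 and Irf7 fell by 2.69, 2.54, 2.14 and 1.58. Immediate-early and stress genes were higher for 6 of 21 and lower for 4, or 6 and 2 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.374). Klf4, Klf6 and Ier3 rose by 4.12, 2.73 and 1.96, and the heat shock gene Hsph1 fell by 2.02. The hepatocyte and adipocyte lists, at −9.04 and 5.72, differed beside these lists too.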

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

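No test in this part was chosen after the result was seen, although some of the genes searched for an outlying array were named after their values were seen.

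Among 172 sets of 4 values on the cΔex3-labelled arrays, 7 held an array whose gap to the nearest of the others took up most of the range. Chance gives about 1 in 20, so this count does not exceed chance. Array 4 stood low for 6 genes. Its level was 4.12 for Lamb1 against 4.88 to 4.94 on the others, and −0.97 for Emcn against 0.08 to 0.18. For Cd34 it was 4.72 against 5.59 to 5.64, for Pi16 1.83 against 3.02 to 3.20, for Pdgfb 2.07 against 3.16 to 3.28 and for Apcdd1 −0.61 against 0.64 to 0.86. Array 2 stood low for Trps1, at 0.20 against 0.86 to 0.99. The group of 3 control-labelled arrays was not tested in this way.

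Probes without a gene name here lay outside the comparisons of named genes. Of 18686 tested, 2345 were higher and 6657 lower on the cΔex3-labelled arrays (limma, adjusted p under 0.05).

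Of the 35 splits of the 7 arrays into 3 and 4, only the labelled one gave as many genes past the threshold. It gave 9569, against at most 1949 in the others. The smallest share that this test can give is 1 in 35, so it does not exclude chance. Every other split also put arrays of both labels on the same side, where the difference between the labels counts as spread. Chance cannot be excluded for the number of gene lists either, since 16 of the 35 splits gave as many lists as the 10 found. The highest other split gave 14.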

How the results depend on the processing

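Slide row as a block, each slide row alone and the fit without cΔex3-labelled arrays 1 and 4 were chosen after the result was seen; the other settings were fixed before. Of 4038 values of 170 chosen genes over up to 24 settings, 3723 kept their direction and their side of the threshold, 273 kept only their direction and lost the threshold, 29 passed it newly and 13 reversed. With the Y-linked covariate 721 genes were higher and 1014 lower, and within slide row 2, with 1 control-labelled array assumed to vary like the others, 524 and 715 were, with 1 list lower; both use fewer residual degrees of freedom, and the cause was not tested further. Within slide row 1, with 1 cΔex3-labelled array under the same assumption, 3991 were higher and 4404 lower, and with slide row as a block 3553 and 4369. Leaving out 1 array at a time gave 3243 to 4922 genes higher, 3995 to 5568 lower and 0 to 1 lists lower, the 1 without control replicate 2. Chosen genes that lost the threshold numbered 8, 9 and 8 without control replicates 1 to 3, and 6, 5, 3 and 2 without cΔex3 replicates 1 to 4. Camera with an estimated correlation called 0 lists higher, and fry called 18 higher and 4 lower.

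The reversed values were those of Ctnnb1, at 0.53 with normexp, 0.47 with quantile normalisation, 0.52 in the series values, 0.02 with arrays of 1 mouse and 0.029 in slide row 1; of Dll3 at 0.13 and Nkd2 at 0.18 with the mean of probes; of Itga8 at 0.39 with arrays of 1 mouse and 0.19 in slide row 1; of Ddx3y at 0.17 and Kdm5d at 0.34 with the Y-linked covariate; and of Lcn5 at −1.73 and Gpx5 at −0.29 in slide row 1, which holds cΔex3-labelled array 1 alone. Averaging probes joins those of Dll3 and Nkd2 that differ in sign; the cause of the others was not tested. Genes higher made up 45.3% of calls, against 53.9% with quantile normalisation, 53.8% with normexp, 54.1% in the series values and 35.8% with median centring, and the median difference of all genes was −0.08, against 0.12, 0.10, 0.11 and −0.31 with these 4 settings. Of the 10 lists called, 9 were called in 24 of 24 settings that kept camera, and Notch receptors and targets in 15.

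With the replicate block 4493 genes were higher and 4980 lower. Deviations of same-numbered arrays correlated at −0.009, −0.0009 and 0.018, and those of differently numbered arrays at −0.091 to 0.089. The numbers thus gave no sign of pairing, but deviations from the means of so few arrays cannot exclude it. A slide or scan block was not run, since the files give 1 slide and 1 scan. Signal over background limits the genes given as bounds.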

Other observations

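All tests in this part were chosen after the result was seen, several were revised after a first run, and the lists for tissues outside skin were written after the most changed genes had been seen.

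Genes of mesothelium, the lining of the body cavities, were higher on the cΔex3-labelled arrays for 6 of 8 and lower for 2. Wt1 rose by 5.08 ± 0.39 (SE; limma, adjusted p = 9.18e-05) and Msln by 5.22, Upk1b was at least 35.8-fold higher (adjusted p = 0.000185), and the keratin genes Krt8 and Krt18, also made by hepatocytes, fell by 2.41 and 2.23, calls that were lost without any of the control-labelled arrays or cΔex3-labelled array 1 or 2, at −2.58 to −2.08. Of the testis list 5 of 9 were higher and 0 lower (limma; also 0 at an unadjusted p under 0.05), and its median lay at the 70.4th percentile on cΔex3-labelled array 4 against 43.3 to 48.5 on the other 3. Prm1, which packs sperm DNA, rose by 7.95, or 7.15 without array 4, and Tnp2 was at least 56.1-fold higher (adjusted p = 0.00135), or 30.4-fold without array 4. Of the other lists, brown adipocyte counted 2 higher and 2 lower of 8, kidney 1 and 4 of 8, heart 2 and 1 of 9, exocrine pancreas 0 and 4 of 8 (limma; 0 and 5 at an unadjusted p under 0.05), lung 1 and 5 of 9 and intestine 1 and 4 of 8.

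Epididymis genes differed between the cΔex3-labelled arrays. Of 16 tested, 5 were higher, 1 lower and 10 did not pass, and the list's median lay at the 13.3th, 57.5th, 74th and 98.8th percentile of named genes on arrays 1 to 4, against 14.2 to 15.4 on the control-labelled arrays. Adam7 stood at −0.54, 2.48, 5.06 and 7.475 on these 4 arrays and Lcn5 at −9.19, 3.64, 6.06 and 7.92. Gpx5 was at least 324-fold higher (adjusted p = 0.0484), with 3 of 4 arrays above background, a call that was lost without any 1 array other than array 1, at 8.03 to 9.58. The bound of Gpx5 was 3166-fold without array 1, 121-fold without array 3 and 133-fold without array 4. Without array 1, Lcn5 passed the threshold (adjusted p = 0.000492, with a range up to 0.185 when other arrays were left out).

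The first pattern weighed is the hepatocyte transcripts on the control-labelled arrays: Alb at 9.74, and 20 of 20 list members, none of them on a list fixed beforehand, lower on the other arrays; how many of them dermal cells express is not known from these data. Probe names out of register with the spots are argued against by the adipocyte list, fixed beforehand, of which 83.3% were called higher against 24% of all genes. A candidate explanation is that these arrays hold material other than the sorted cells, possibly liver. The test set for this and for a minor share of hepatocyte RNA in dermal sheath samples decided neither. Matrix and contractile genes differed by a median of −3.11 (control-labelled minus cΔex3-labelled) with quartiles of −4.20 and −1.40, between the bounds set for either. The cΔex3-labelled arrays carried adipocyte transcripts, and no array gives the level of matrix and contractile genes in dermal sheath cells. Levels within the control-labelled arrays do not decide on a minor share either. Such ranks compare different probes, and the hepatocyte list was written after the brightest genes on these arrays had been seen. The hepatocyte list lay at the 99.8th percentile on each of these arrays. The fibrillar matrix and contractile lists, fixed beforehand, lay at 47.7 to 50.4 and 53.3 to 58.8. By the labels, β-catenin activation belongs to the other group, so it cannot account for the hepatocyte list at the 99.8th percentile on the control-labelled arrays. Whether activation lowered these genes in the other group was not decided, since Wnt targets, with a median of −0.83, went both ways. The tests of these 4 explanations were replaced after earlier ones, on the hepatocyte list or on how the lists rank within an array, had been seen. Those ranks had been read as favouring other material. A sort for YFP would remove hepatocytes unless they carried the reporter, and whether the deposited files belong to other arrays, which the slide numbers leave open, was not tested.

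The second pattern is the adipocyte transcripts on the cΔex3-labelled arrays, where the list, fixed beforehand, was higher by a median of 5.72. Against conversion of dermal sheath cells into adipocytes as the whole cause of transcripts foreign to skin stands the mesothelium list's median of 5.15. That list was written after the most changed genes had been seen, and 2 of its 8 members fell, so it is no independent test. For the adipocyte transcripts alone conversion stays open, as Cd34 at 4.84 decides nothing if marker and transcript can part. The explanation was split in this way, and the test of the material changed from a percentile, after a first run. Adipose tissue in the samples, which this difference is consistent with, may account for all of it, and mesothelium, which covers fat of the body cavities, would come with it. Dermis also holds adipocytes, and a sort for YFP would remove them unless they carried the reporter. β-catenin activation in the cells that the labels name stays untested by these arrays.

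The third pattern is the epididymis transcripts. A higher share of probes above background on arrays 1 and 4 is argued against, since array 1 lay below arrays 2 and 3 by a median of −7.56. An uneven share of epididymis, which might come with fat dissected beside it, stays open: 75% of the members not looked at before, 6 of 8, were lowest on array 1, where 80% was required. That test first used all 16 members, of which 13 were lowest on array 1, enough to pass, was then limited to the 8, and was run with looser bounds, the first ones being put back after the 75% had been seen. The design names no biological difference among these 4 arrays, and none was tested.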
